A study of Mus musculus with 2 samples.

How the data were processed

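Sertoli cells were isolated from the testes of adult male Swiss mice by 2 rounds of enzymatic digestion and were collected, per the labels' protocols, as the material held back by the finer of a pair of cell strainers. They were not cultured. Total RNA of 1 control preparation and 1 preparation taken 1 month after 25 mg/kg busulphan was labelled with Cy3 and hybridised to 1 array each. The labels do not say how many mice each preparation pools. Both arrays carry the same scan time per the file headers, so no scanning batch separates them. A shared scan time does not cover earlier steps. Each preparation, labelling and array belongs to 1 group and cannot be told apart from it.

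The deposited intensity values were made with Agilent Feature Extraction 11.5.1.1, per the file headers, which subtracts a background surface, divides out a multiplicative trend across the slide and gives dim spots a surrogate value. Each array held 15744 spots, of which 536 were control spots, and 15208 non-control probes of 60 bases with 1 spot each. The deposited log2 table of the series equals log2 of the processed signal minus a constant per array, 10.03 for control and 9.82 for busulphan, within 0.01 of the array's 75th percentile. Its median was -2.94 for control and -2.77 for busulphan. Its scale, centring and direction therefore follow from the values, and no genes were centred.

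The main values were log2 of the processed signal minus the array's 75th percentile of it over non-control probes, which was a signal of 1046 on the control and 905 on the busulphan array. The 4 probes marked as outliers on either array were left out. Probes had to be well above background on at least 1 array, which 12862 were, and 11504 were so on both. A gene took its probe with the highest mean over both arrays. A probe well above background on 1 array only carries a bound, the bright value against the higher of the lowest signal among probes well above background on the dim array and the dim probe's own. This applied to 927 genes. A spot saturated on 1 array also gives a bound, for 99 genes, with 106 probes saturated on the control and 18 on the busulphan array, 6 of them on both, which were given no fold. For 8 genes the bound pointed the other way and they entered with a log2 ratio of 0, a rule set after their values were seen. Bounds are written as at least so many fold, and stand at their bound in medians and counts. Fewer bright germ cell transcripts can be sized in full because the control spots saturate.

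Gene names came from the files' accessions through a table of GRCm38.p6 genes, without versions, for 13300 probes, and 1908 kept the name in the files. Coordinates are those of the files, on mm9 (NCBI37). The files do not say whether a probe lies in an exon or an untranslated region, and no genome was used here. One probe of the named genes, that of Rhox5, has no coordinates in the files.

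With 1 array per group there was no test. A gene was called higher or lower by a rule of size, a log2 ratio of at least 1 either way. A gene list was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins, and read as apart below percentile 2.5 or above 97.5. These percentiles describe 2 libraries and give no probability about the treatment. The 26 lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 highest and 12 lowest ratios among named genes measured on both arrays without saturation, the 5 highest and 5 lowest bounds, and in each list the 2 highest and 2 lowest members, with Amh, Sox9, Wt1, Clu, Fshr, Rhox5, Gdnf, Kitl, Prm1, Prm2, Tnp1 and Tnp2 whatever their value. Some genes that this rule takes are not reported here. Intervals on differences between list medians are 95% intervals from 2000 resamplings of genes, which are not replicates.

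Alternatives were normexp background correction (offset 50) on mean and local background signals, scaling by the median, by quantiles, by the 75th percentile of probes bright on both arrays, by housekeeping genes, by loess or not at all, other filters on dim and saturated probes, measured values in place of bounds, the median over probes, the deposited log2 table, thresholds of 1.5-fold and 4-fold, unmatched random lists and lists without shared members. Scaling to 6 spike-in control probes with 20 spots each was added after the data were examined. The gene counts were tested on simulated data for 9441 genes with the software's spot error. With no gene changed, 30 genes passed 2-fold. Of 200 genes changed 1.5-fold, 3-fold and 8-fold, 2.5%, 99.5% and 100% were called. The changed genes were drawn from the brighter genes only and no simulated spot was saturated, so these rates do not cover dim or saturated genes. The list percentiles were tested on the real ratios, shuffled between genes of similar mean level and without simulated spot error. Of 200 random lists of 20 genes without an effect, 6% lay outside the percentile limits, and of 200 raised 4-fold, 96% lay above them. Shuffled ratios are independent between genes, so these rates do not cover lists whose genes vary together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, with limma 3.58.1 in R 4.3.3 for normexp, quantile and loess values.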

Results

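Gene expression was measured in preparations labelled as isolated Sertoli cells, the somatic cells of the seminiferous tubule that nurse developing germ cells, from adult male Swiss mice aged 3 months. The control preparation also held abundant germ cell RNA, since its spots for Prm1, Prm2, Tnp1, Tnp2, Oaz3 and Pgk2, transcripts of meiotic and later germ cells, were saturated. Busulphan is an alkylating drug that is widely used to deplete the germ cells of the testis. One preparation came from untreated mice and the other from mice given 25 mg/kg busulphan 1 month earlier, and the series set out to evaluate how the Sertoli cell profile differs after the drug. Each preparation was hybridised to 1 single-colour array, so that n = 1 per group, no difference below has a replicate check and no p-value is given. All directions compare these 2 libraries, not the treatments in general. The control array had 12302 of 15208 probes well above background (80.9%) and the busulphan array 12064 (79.3%). The number of arrays limits the precision. The only error the files hold is that of the spots. The scanner software's own error on a gene's log2 ratio had a median of 0.20. The median SD of log2 signal between replicate spots was 0.06 for the 6 spike-in control probes well above background and unsaturated. Over all 42 control probes with at least 5 spots it was 0.12.

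Of 9441 genes compared, 2952 (31.3%) were at least 2-fold higher in the busulphan library and 2784 (29.5%) at least 2-fold lower, and 3705 lay within 2-fold. A difference of at least 16-fold was seen for 125 higher and 515 lower genes. The SD of the log2 ratio over genes was 2.10, far above the software error, and Pearson's r of scaled log2 signals across genes, which are not replicates, was 0.79. When the arrays were scaled to the spike-in controls, a choice made after the data were examined, the counts became 1524 higher and 4383 lower. Folds of dim genes shrank with normexp background correction, under which Amh, Adgrb1, Egr3, Hsd17b3, Lyve1, Slc4a1, Snrpn and Tek lay within 2-fold. Counts of higher genes with the main scaling are relative to the 75th percentile of the array.

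Transcripts of haploid germ cells were the lowest group in the busulphan library. All 25 spermatid markers compared were at least 2-fold lower, with a median log2 ratio of -5.28 (38.9-fold). The control spots of 10 members were saturated, and these carry lower bounds of the fold. Among genes measured on both arrays without saturation, each by its brightest probe and clone and predicted-gene names left out, Tssk6 was lowest. This testis-specific serine kinase was 156-fold lower (log2 -7.29, software error 0.20). Its probe lies on chromosome 8 at 72426918 to 72426977 of mouse build mm9. Oaz3, an antizyme of spermatids, was at least 145-fold lower, and Tnp2, a transition protein that packs sperm chromatin, at least 98.3-fold lower. Prm1, Prm2 and Tnp1, which serve the same packing, were saturated on the control array and were at least 3.55-fold, 5.31-fold and 8.12-fold lower, and other saturated Prm1 probes gave log2 bounds of -2.93 and -3.65. The list's median lay at percentile 0.0 of 10000 random lists matched on mean level, whose own median was -0.33.

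Meiotic transcripts were also lower, by less. Of 28 spermatocyte markers, 24 were at least 2-fold lower, none higher and 4 within 2-fold, with a median log2 ratio of -2.99 (7.94-fold) at percentile 0.0. Pgk2, the glycolytic kinase of meiotic and later germ cells, was at least 38.0-fold lower, and the meiotic cyclin Ccna1 was 29.3-fold lower. Sycp1, a synaptonemal complex protein, had a log2 ratio of -0.84 and the recombinase Dmc1 0.49, the latter below 0 with spike-in scaling. The spermatid median was below the spermatocyte median by a log2 difference of -2.29 (95% resampling interval over genes -3.39 to -1.58).

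As a list, markers of spermatogonia, the stem and early germ cells, did not share this direction. Of 16 compared, 8 were at least 2-fold higher, 1 lower and 7 within 2-fold, with a median of 0.82 at percentile 87.9, inside the range of random lists. The sign of this median turned with spike-in scaling, to -0.06. Gfra1, the GDNF co-receptor of spermatogonial stem cells, was 5.96-fold lower, although its other probe gave -0.35, and Utf1 had a log2 ratio of -0.82. Neurog3, Kit and Bcl6b, picked after their values were seen, were negative too, at -0.79, -0.45 and -0.39. The highest members were the integrin Itga6 (18.9-fold) and the proteoglycan Sdc4 (14.3-fold), which somatic cells also express, and 5 of the 16 stand in another list. The median mixes these members, so it cannot tell how spermatogonia themselves changed. The difference between the spermatocyte and spermatogonial medians was -3.81 (interval -4.86 to -2.58). Of 12 pluripotency and early germ cell genes, 3 were higher and 4 lower, with a median of -0.32 at percentile 26.7. Zfp42 was 5.28-fold lower, the germ cell helicase Ddx4 8.67-fold lower, and Sall4 3.14-fold higher, with a second Sall4 probe at -0.51.

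**Figure D1:**
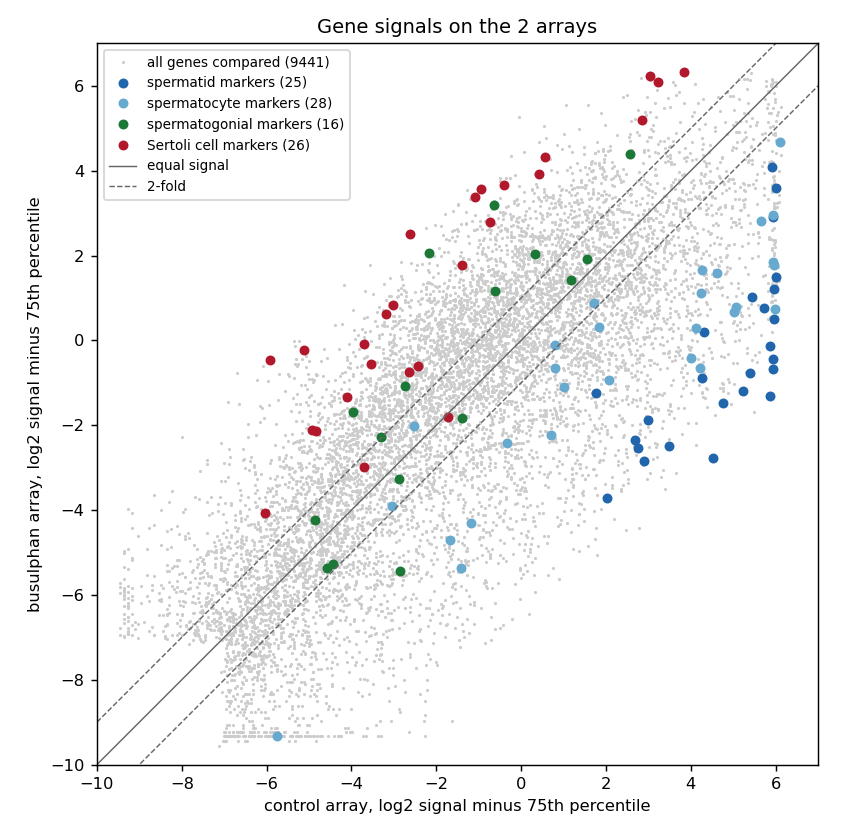
Scaled log2 signal of each of 9441 genes on the control array (horizontal axis) and the busulphan array (vertical axis), with 4 marker lists in colour and dashed lines at a 2-fold difference. Spermatid markers lie far below the line of equal signal (median log2 ratio -5.28), spermatocyte markers below it (-2.99), and Sertoli cell markers above it (3.18). The saturated control spots lie near 6 on the control axis, among other bright spots.

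Sertoli cell markers had, with inflammatory cytokine genes, the highest medians of the lists. Of 26 compared, 24 were at least 2-fold higher in the busulphan library and none lower, with a median log2 ratio of 3.18 (9.08-fold) at percentile 100.0. Sox8 and Sox9, transcription factors of Sertoli cell identity, were 43.9-fold and 34.8-fold higher, and the FSH receptor Fshr 29.4-fold higher. Another Sox8 probe gave a log2 ratio of 3.19, and other Sox9 probes gave 4.96 and 2.24. The probe for Sox9 lies on chromosome 11 at 112647008 to 112647067 of mm9. The homeobox gene Rhox5 was 11.2-fold higher, Wt1 had a log2 ratio of 3.53, and Clu, an abundant secreted chaperone, was at least 9.18-fold higher with a saturated spot. Amh, the hormone of immature Sertoli cells, was 3.94-fold higher at signals of 15.9 and 54.0, near background. Krt18, a keratin of immature Sertoli cells, had a log2 ratio of -0.06 and Gata4 one of 0.73, with another Gata4 probe at 3.52. The median of the Sertoli list was above that of the Leydig list by 2.51 (interval 1.06 to 3.49), and 7 of its members stand in another list.

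Other cell types of the testis did not share one direction. Of 19 macrophage markers, 13 were at least 2-fold higher and 3 lower, with a median of 2.69 at percentile 100.0 and a mean of 1.32. The complement gene C1qc was 16.3-fold and the mannose receptor Mrc1 12.2-fold higher, while Aif1 was at least 44.1-fold lower, saturated in the control, and the Fc receptor Fcgr3 13.3-fold lower. Leydig cells are the androgen-producing cells between the tubules. Of 19 Leydig cell markers, 8 were higher and 1 lower, with a median of 0.68 at percentile 77.2 that turned to -0.21 with spike-in scaling. Star, which moves cholesterol into mitochondria, was 11.7-fold higher, Akr1b7 17.8-fold higher and Hsd17b3, the last step of testosterone synthesis, 3.80-fold lower, and Fdx1 had a log2 ratio of -0.86 with its other probe at 1.33. Of 11 peritubular myoid and smooth muscle markers, 6 were higher and 1 lower, with a median of 1.14 at percentile 97.0; with normexp background correction the percentile was 97.6, past the upper limit. Ptch1 and Cald1 were 3.39-fold and 3.18-fold higher, another Cald1 probe gave -0.27, and Actg2 had a log2 ratio of -0.75. Endothelial markers had a median of -0.27 at percentile 16.1, with 3 of 18 higher and 4 lower, among them Robo4 at 7.20-fold and Lyve1 at 5.49-fold higher and Sox17 at 9.95-fold and Tek at 2.46-fold lower, with a second bright Sox17 probe at -2.93 and another Tek probe at 0.45. Red blood cell genes had a median of -1.17 at percentile 6.49, with 1 of 7 higher (Alas2, 5.88-fold) and 4 lower (Hemgn, 77.5-fold, and Slc4a1, 2.87-fold, among them), and Hbb-bt had a log2 ratio of -0.73. Lcn9 was the 1 epididymal marker compared, of 4 on the array, at -0.86, too few for a percentile.

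**Figure D2:**
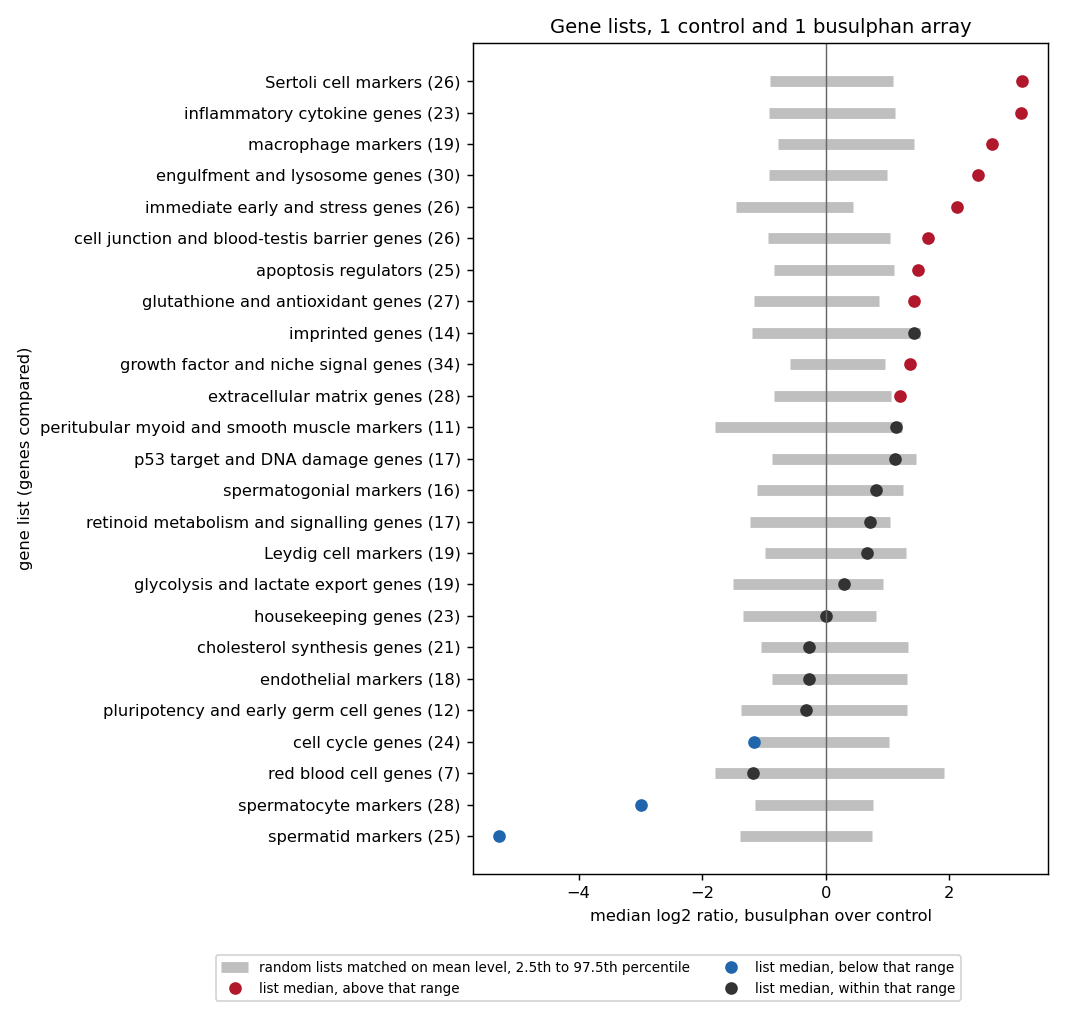
Median log2 ratio, busulphan over control, of 25 gene lists (points; number of genes compared in brackets), with grey bars for the central 95% of medians of 10000 random lists matched on mean level. Sertoli cell markers (3.18) and inflammatory cytokine genes (3.17) lie farthest to the right of their bars, and spermatid markers (-5.28) farthest to the left.

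Genes for the functions of Sertoli cells were mostly higher, in a library in which Sertoli cell markers were higher too. The median of those markers (3.18) was above that of each list in this paragraph. Of 26 cell junction and blood-testis barrier genes, 19 were at least 2-fold higher and 1 lower, with a median of 1.66 (3.15-fold) at percentile 99.98. Ocln and Cldn11, tight junction proteins, were 24.8-fold and 22.8-fold higher, another Ocln probe, dim in the control, gave at least 0.87, and Nectin3, an adhesion molecule of germ cells, was 17.3-fold lower. Of 34 growth factor and niche signal genes, 18 were higher and 5 lower, with a median of 1.37 at percentile 99.8. Gdnf and Kitl, which sustain spermatogonia, were 6.50-fold and 13.9-fold higher, Wnt4 at least 25.4-fold and Fst 21.9-fold higher. Wnt3 was 58.0-fold lower, with its other probe at -1.62, and Hgf had a log2 ratio of at most -3.53. Without members that stand in a second list, this list lay at percentile 91.7, no longer past the limit. Of 30 engulfment and lysosome genes, through which Sertoli cells clear dying germ cells and which macrophages also express, 26 were higher and 2 lower, with a median of 2.46 (5.50-fold) at percentile 100.0. Tyro3 and Mertk, receptors for dying cells, were 16.8-fold and 15.8-fold higher, Elmo1 was 4.60-fold and Adgrb1 2.05-fold lower.

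Metabolic lists held members in both directions. Glycolysis and lactate export genes had 8 higher and 8 lower of 19, with a median of 0.29 at percentile 82.1 that turned to -0.59 with spike-in scaling. The hexokinase Hk2 was 11.8-fold and Ldhb at least 10.3-fold higher, Hk1 at least 15.0-fold and Eno1 5.79-fold lower, and the 5 unsaturated probes of Hk1 gave log2 ratios from -4.02 to -5.63. Cholesterol synthesis genes had 8 higher and 9 lower of 21, with a median of -0.26 at percentile 19.01. Ebp was 24.1-fold higher and Fdft1 13.1-fold lower, although another Fdft1 probe gave -0.56. Retinoid genes had 4 higher and 2 lower of 17, with a median of 0.72 at percentile 90.6, which passed the upper limit with normexp (98.0) and turned to -0.12 with spike-in scaling. Aldh1a3 was 8.66-fold higher, and Rdh11 was 11.9-fold and Aldh1a2, which makes retinoic acid, 2.10-fold lower. Under an alternative the log2 ratio of Aldh1a2 was -0.56, within 2-fold. Of 27 glutathione and antioxidant genes, 16 were higher and 3 lower, with a median of 1.43 (2.70-fold) at percentile 99.9. Mgst1 was 15.7-fold and Gsta4 9.59-fold higher, while Gpx4, which is abundant in spermatids, and Gstm5 were at least 4.79-fold and 6.99-fold lower.

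Immune and stress genes were higher, beside macrophage markers at a median of 2.69. Of 23 inflammatory cytokine genes, 19 were at least 2-fold higher and none lower, with a median of 3.17 (8.97-fold) at percentile 100.0. The chemokines Ccl7 and Ccl2 were 27.4-fold and 25.5-fold higher, while Tlr4 had a log2 ratio of 0.56, at signals of 12.1 and 15.4, and Il18 one of 0.11, which turned below 0 under 5 other scalings, loess among them. Of 26 immediate early and stress genes, which respond to stimulation within minutes, 20 were higher and 2 lower, with a median of 2.12 (4.34-fold) at percentile 100.0. Klf6 was 10.9-fold and Myc 8.53-fold higher, the heat shock gene Dnajb1 3.33-fold and Egr3 4.15-fold lower. The log2 ratio of Dnajb1 was -0.75, within 2-fold, under an alternative, while its other probe gave -2.89. Of 25 apoptosis regulators, 15 were higher and 6 lower, with a 2.83-fold higher median at percentile 99.8. Birc3 was 16.5-fold and Casp8 10.1-fold higher, and Fasl 7.81-fold and Diablo 5.36-fold lower. Another Birc3 probe gave a log2 ratio of 2.23, and another Fasl probe -1.25. Of 17 p53 target and DNA damage genes, 10 were higher and 1 lower, with a median of 1.11 at percentile 89.8, inside the range of random lists. The death receptor Fas was 29.8-fold higher, with another probe at a log2 ratio of 2.72. The cell cycle inhibitor Cdkn1a had a log2 ratio of 3.46 and Mdm2 had -0.69 (another probe gave -2.80, and the median over probes -1.75). Tnfrsf10b was 7.84-fold lower, with a second probe at -1.37 and another, dim in the control, at 0.59 or above.

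Of 24 cell cycle genes, 12 were at least 2-fold lower and 2 higher, with a median of -1.16 (2.24-fold) at percentile 1.95. The mitotic kinase Plk1 and cyclin Ccnb2 were 24.9-fold and 11.8-fold lower. The higher members were Mcm4 (2.70-fold), a DNA replication helicase subunit, and Tyms (2.16-fold), which makes thymidylate. With spike-in scaling these were within 2-fold, at log2 ratios of 0.55 and 0.23. The cell cycle list no longer passed the limit with normexp, with no filter on dim probes or with the median over probes, at percentiles of 6.14, 2.86 and 10.8. Of 28 extracellular matrix genes, 15 were higher and 2 lower, with a median of 1.21 at percentile 98.9. Thbs1 and Timp1 were 21.6-fold and 20.2-fold higher, Postn 4.63-fold and Col5a1 2.42-fold lower. Another Col5a1 probe gave -0.43, and under an alternative the gene was at -0.85, within 2-fold. The matrix list fell short of the limit with normexp, loess or the median over probes, at percentiles of 97.0, 97.3 and 91.6. Of 14 imprinted genes, 9 were higher and 2 lower, with a median of 1.43 at percentile 96.5, which passed the limit with quantile normalization (98.3), loess (97.8) or unmatched random lists (98.8). Peg3 and Gnas were 11.3-fold and 5.26-fold higher, and Cdkn1c and Snrpn 9.20-fold and 2.36-fold lower. Housekeeping genes had a median of 0.00 (between -0.84 and 0.63 over the scalings) at percentile 70.4, with 6 of 23 higher and 4 lower; Rab7 was 5.14-fold and B2m 4.17-fold higher and Tbp 11.3-fold lower, and Ywhaz was 4.16-fold lower by its brightest probe and higher by another, at 2.41.

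Genes measured on both arrays without saturation were also ranked for the highest ratios, each by its brightest probe and clone and predicted-gene names left out. The lipase Lipg (60.5-fold, signals of 10.1 and 528) and the sodium channel subunit Scn3b (45.0-fold) stood first. The platelet chemokine Pf4 (44.3-fold), Sox8 and the leukocyte actin-bundling protein Lcp1 (43.9-fold each) came next. Igfbp3, Kif21a, Serpina5, the microglia and macrophage receptor Trem2, the iron exporter Slc40a1, Ctnnal1 and Rln1 followed, between 41.0-fold and 35.6-fold higher. Serpina5 was the brightest of these, at signals of 1004 and 34660. Other probes well above background on both arrays gave lower log2 ratios for Scn3b (3.29), Sox8 (3.19) and Igfbp3 (3.24). Sizes and order of this group depended on the background correction: with normexp, whose offset shrinks the folds of dim spots, the log2 ratio of Lipg was 3.22, of Pf4 3.37, of Sox8 3.48, of Lcp1 2.76, of Trem2 3.14 and of Rln1 2.75, while that of Serpina5 was not below 4.43 under any alternative. By the same rule on names, Olr1, Wnt4, Tha1, Gpr84 and Il10 had the highest bounds among genes not well above background in the control. These ran from at least 28.7-fold to at least 18.6-fold higher. With normexp these were log2 ratios of 1.57 (Il10) to 2.20 (Olr1).

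After Tssk6, the lowest ratios by the same rule belonged to Oxct2a, a ketone body enzyme of spermatids, at 147-fold lower, and Ppp2r2b, a phosphatase subunit, also at 147-fold. A second Oxct2a probe, unsaturated on both arrays, gave a log2 ratio of -7.37, below that of Tssk6. Prkar2a, a subunit of protein kinase A, was 120-fold lower, Grin2b 114-fold and Dclk1 100.01-fold. Probes of these genes differed. A second bright probe of Grin2b gave -6.43 and one of Ppp2r2b -5.14, whereas the other probes of Prkar2a gave -0.66 and -0.90 and one of Dclk1 -0.17. Grin2b and Dclk1 also had probes not well above background in the control that gave ratios of at least 1.09 and up to at least 3.24. Hspa1l, a heat shock protein of spermatids, was 96.0-fold lower, Tuba8 92.1-fold, Klk1b9 92.0-fold, Kif17 87.2-fold, Pdzk1 87.0-fold and Cd3d 85.5-fold. Klk1b9 belongs to a family of near-identical kallikreins that 1 probe may not separate. Nmur1, Atp2b2, Trpm8 and Cldn13 were among those with the lowest bounds of genes not well above background in the busulphan library. Clone and predicted-gene names were left out here too. These bounds ran from at least 77.4-fold to at least 36.8-fold lower. With normexp Nmur1 had a log2 ratio of -3.18 and Cldn13 had -2.20. Among the 2644 genes with more than 1 probe, 173 had probes at least 2-fold higher and others at least 2-fold lower.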

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

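The tests in this part were chosen after the result was seen. Spike-in control probes, which report RNA added in known amounts and are not used in the main values, were brighter on the busulphan array. All 6 usable probes showed it, with a median log2 ratio of 0.68 before scaling (1.61-fold) and a range of 0.31 to 0.99, against an SD of 0.08 for the ratio of single spots. The signal was noticed because it stands above that of the control array. A brighter hybridisation or scan of the whole array is argued against by the 75th percentile of the other probes, which was lower on the busulphan array by a log2 ratio of -0.21, and by the bright corner spots at -0.35. Less labelled sample RNA, or more spike-in, in the busulphan reaction stays open and the pair cannot be told apart: the spike-in ratios all have 1 sign but span 0.67, more than spot noise, so no single amount accounts for them all. If the spike-ins were taken as equal, the log2 ratios of the named genes would move by -0.88. No biological explanation was tested.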

How the results depend on the processing

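Spike-in scaling was added after the data were examined; the others were planned. The counts of genes at least 2-fold higher and lower stayed within 1.5 times their main values of 2952 and 2784 except with spike-in scaling (1524 and 4383; 25.8% of calls higher against 51.5%, from its constant of -0.88) and a 4-fold threshold (1360 and 1674, since fewer genes pass a higher limit). Other scalings moved the median log2 ratio over genes by -0.21 (none), -0.20 (housekeeping), -0.17 (median) and 0.17 (probes bright on both arrays). For 25 lists, 388 of 400 results under alternatives kept their side of the percentile limits, and 19 lists did so in all 16 alternatives. The exceptions are given as shift of the median against random lists. With normexp, myoid 1.38 and retinoid 0.55 became past the limit, and extracellular matrix 0.71 and cell cycle -0.84 no longer were. With loess, imprinted 1.22 passed and extracellular matrix 0.85 did not. Imprinted also passed with quantiles (1.29) and unmatched lists (1.35). With the median over probes, extracellular matrix 0.60 and cell cycle -0.67 did not pass. Cell cycle did not pass without the filter on dim probes (-1.11), nor niche signals without shared members (0.60). The shared niche members left out were Gdnf, Kitl, Inha and Dhh, at 2.70 to 4.04, and Igf2, at 0.74. The cause of these moves was not tested. Over all alternatives the shift stayed between 2.87 and 3.33 for Sertoli, -5.77 and -4.57 for spermatid, and -3.06 and -2.42 for spermatocyte markers. Of 1953 values of 141 named genes, 1412 moved by less than the software error, 539 by more, and 2 past 2-fold reversed: with the median over probes Dclk1 became 1.32 and Ywhaz 0.17, because their probes disagree. Il18, Dmc1, Fdx1, Gata4, Krt18, Lcn9 and Tlr4, within 2-fold, also changed sign under at least 1 alternative. Of genes past 2-fold in the main values, Dnajb1, Aldh1a2, Col5a1, Mcm4, Tyms, Cald1, Ptch1, Sall4 and Prm1, among others, fell within 2-fold under at least 1 alternative. Leaving out a replicate was not possible with 1 sample per group. No paired analysis was possible because each group has 1 sample and no test. Dim signals limit Amh and Lipg, which are near background on the control array, and saturation limits the protamines.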

Other observations

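Genes on the X chromosome stood apart from the autosomes, the test of which was fixed before its result was seen. Of 292 X-linked genes compared, 174 (59.6%) were at least 2-fold higher in the busulphan library and 36 (12.3%) lower, against 30.4% and 30.0% of 9056 autosomal genes. Their median log2 ratio was 1.54 against 0.03, while the medians of the 19 autosomes lay between -0.25 and 0.53. The 279 X-linked genes that stand in no marker list had a median of 1.52. Some X-linked genes were far lower, among them the sperm tail anchor Akap4 (-6.16), Zcchc13 (-5.91), Tsga8 (-5.62) and Rhox3a (-4.25), picked after their values were seen.

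Several enzymes and chaperones have a somatic copy and a testis copy used in later germ cells. The pairs named here were chosen because of their values, from no fixed list, and serve only as examples. Phosphoglycerate kinase Pgk1 was at 1.48 and its retrogene Pgk2 at or below -5.25, the pyruvate dehydrogenase subunit Pdha1 at 1.54 and Pdha2 at -3.87, cytochrome Cycs at 2.57 and Cyct at -2.94, and the heat shock gene Hspa1b at 2.32 and Hspa1l at -6.59. The ketone enzyme Oxct1 was at -0.70 and Oxct2a at -7.20, and Gk was lower too, at -1.18 beside Gykl1 at or below -4.48. The somatic and testis copies named here kept their signs under each scaling. Among 97 families of at least 10 genes that share the start of a symbol, 7 lay above and 6 below the limits of matched random lists. Chance gives 4.85 outside the upper and lower limits together. These families were also looked at after the fact. The Wnt receptors Fzd had 9 of 10 members at least 2-fold higher (median 1.92), the protocadherins Pcdhb 12 of 18 (1.24) and the aldehyde dehydrogenases Aldh 10 of 16 (1.75). The Adam proteases, several of which act on sperm, had 10 of 19 lower (-1.86), and the phosphodiesterases Pde 11 of 16 (-1.82). These medians kept their sign under each scaling.

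All tests in the next paragraphs except that of X-linked genes were chosen after the result was seen. Spermatid markers had lower ratios than spermatocyte markers, and spermatogonial markers were not lower as a list. The higher of the spermatid and spermatocyte medians was at most -2.46 under 9 scalings and background settings. Most of these settings shift nearly every gene by the same amount, so this outcome was largely fixed. A shift of that kind cannot set the lists apart from each other. A trend on probe GC content and signal level explained 2.58% of the variance of log2 ratios over genes. With it removed, the members of both lists had a median of -3.66 (interval -4.30 to -2.97). So small a trend could change most ratios little, so this shows only that the fitted trend left most of the shift in place. Fewer meiotic and later germ cells among the isolated cells is a candidate explanation. The X chromosome is largely, not wholly, silenced in those cells, so their loss predicts a relative excess of X-linked transcripts. The X-linked minus autosomal median was 1.51 (interval 1.28 to 1.79), and between 0.78 and 1.70 under the alternatives. Even so, 36 of 292 X-linked genes were at least 2-fold lower, Akap4 among them, which full silencing would not predict. Fewer germ cells remains a hypothesis about 2 preparations. Lower transcription within the germ cells that remain, or a difference in how many germ cells stayed attached in digestion and straining, were not separated from the drug.

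Somatic marker lists did not move alike, with Sertoli and macrophage markers higher and endothelial markers at a median of -0.27. A single lower share of germ cells would raise every somatic type alike only if germ cells do not express the markers. That was not checked. The Sertoli median was above the endothelial one by 3.46 (interval 2.48 to 4.37). These lists were compared after their medians were seen to lie far apart, so this difference cannot decide that explanation. After the trend on probe GC content and level was removed, the difference was 3.40 (interval 2.62 to 4.51). That trend explained 2.58% of the variance of log2 ratios over genes, so its removal could change most ratios little. The fitted trend left most of the difference in place, and no more is concluded from it. Which somatic types were held back by the strainer, changes of expression within Sertoli cells, and cells that entered the testis may each contribute and were not separated here. Macrophages are one candidate source of the inflammatory transcripts, but their markers were split. Of 19, 13 were at least 2-fold higher, with Mrc1 and C1qc highest at 3.61 and 4.03. The 3 lower members were Aif1, Fcgr3 and Msr1 (-3.73). Adgre1 (0.03), C1qb (0.27) and H2-Ab1 (-0.56) lay within 2-fold. The control signal of Aif1 was saturated at 62716, against 110.8 for Mrc1 and 34.1 for C1qc. Whether Aif1 reports macrophages in these preparations was not tested, so its lower ratio cannot be read against them. The inflammatory median differed from the macrophage one by 0.47 and from the Sertoli one by -0.02. Each difference had an interval that held 0, so these medians do not favour either source.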
